A study of Mus musculus with 14 samples.

How the data were processed

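RNA sequencing and reduced representation bisulfite sequencing (RRBS, which reads CpG methylation in fragments cut by a restriction enzyme) were run on mammary tumours of FVB mice that carry the SV40 large T antigen transgene. The offspring were about 25 weeks old and ate control diet. Their mothers had eaten either control diet or a diet with 250 mg/kg genistein, a soy isoflavone, starting at 4 weeks of age and ending at weaning. Each assay had 3 control libraries and 4 maternal genistein libraries. The labels name no batch, and they do not say whether libraries of one group came from separate litters, so p-values measure only the spread between these samples.

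Per the submitters' processing notes, FastQC, STAR, HTSeq, DESeq, Trim Galore, Bismark and R 3.6.1 were used on builds GRCm38 and mm10, which share coordinates. Which step each tool served, and the versions of the others, are not given in the sources used here. Read counts of RNA per library were not used here. Per the file headers, the authors gave each called gene a mean normalised count (a signal over all libraries), a DESeq log2 fold change with its standard error, p-value and adjusted p-value, and the matching edgeR log2 fold change and false discovery rate. The authors' deposited table held 1333 lines for 1324 genes, and repeated lines of a gene were used once. It lists only genes with a DESeq adjusted p under 0.05, so no gene outside it was analysed here. All 1324 gene identifiers matched a symbol, and 1269 were placed by symbol on assembly GRCm38.p6.

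For RRBS, the authors deposited methylated and total read counts per library, the percent methylation, a p-value and a q-value at 4327 CpG sites. Tested on the file, every listed site had a q-value of at most 0.00959, an absolute difference of at least 25.0 percentage points and a coverage of at least 10 reads in every library. The deposited p-values equal those of a likelihood-ratio test on reads pooled within groups, with no term for spread between tumours. The deposited region table gives mean methylation per group as a fraction, printed here as percent. Another deposited table pairs called genes with listed sites. Differences in the RRBS tables are maternal genistein minus control, checked against the group levels.

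The header of the RNA table does not name the numerator of the fold change. Positive values are read here as higher in maternal genistein tumours. The basis is DNA coverage: chromosomes with more positive genes had higher relative RRBS coverage in the maternal genistein libraries (Pearson's r = 0.901 over 20 chromosomes), and the opposite reading turns the sign of every RNA statement. This assumes that expression follows DNA dosage and that both assays sampled the same or like tumours. The labels do not say whether RNA and RRBS libraries with the same number come from the same tumour. Relative coverage is the log2 read coverage at listed sites, less each site's mean over libraries and each library's autosomal median.

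From the deposited read counts, a quasi-binomial model compared the groups at each site. The dispersion was the Pearson chi-square over residual degrees of freedom with a floor of 1, and an F test gave the p-value. Benjamini-Hochberg adjustment ran over the 4327 listed sites, which is lenient because the list had already been selected for this comparison. Single sites and regions were also compared with a two-sided exact permutation test of library levels, whose smallest p with 3 and 4 libraries is 0.0286. In simulated data at the 4327 sites with the spread of the listed sites, 5.23% of unchanged sites had a quasi-binomial p under 0.05 when 200 other sites changed by 50 points. Of those 200 sites, 70.5% had a p under 0.05 and 6% passed the adjustment. With changes of 25 points, 24% had a p under 0.05 and 0% passed, and 6.11% of unchanged sites had a p under 0.05. The pooled-read test gave a p under 0.05 at 53.3% of the unchanged simulated sites with changes of 50 points, and at 55.2% with 25 points. The simulated spread comes from the listed, already selected sites, so these rates need not hold for CpGs that were not listed. Baseline levels were drawn from the middle of the scale, so the rates need not hold at sites near either end.

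Members of 27 gene lists, fixed before the data were examined, were compared with the other called genes by a two-sided Fisher's exact test of higher against lower, adjusted over the lists. A count adjusted over the list alone needs p-values of genes that were not called, which were not used here. Genes are not independent replicates. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only, since PCR reads and neighbouring CpGs are not independent. Permutation tests with 100000 resamples were used for correlations over chromosomes.

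The rule for named genes was written at the same stage as the gene lists. For RNA these were the 10 largest folds in each direction with a mean normalised count of at least 50, the 5 lowest p-values in each direction, and called list members (all of up to 4, otherwise the 4 with the lowest p). For RRBS they were the 5 sites with the lowest p in each direction inside or next to a named gene, and the 5 regions with the largest difference in each direction. For the integrated table they were the 10 genes with the largest difference at a promoter site. For RNA, genes with only a predicted-gene or clone symbol were passed over. Some genes and regions that the rule takes are not reported here. Alternatives covered thresholds, expression and coverage minimums, sex chromosomes, merging of sites within 1000 bases, leaving out each library, and the replicate number as a block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Leaving out RNA libraries, another RNA normalisation and an RNA block were not run, because RNA values per library were not used here.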

Results

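The data compare mammary tumours from offspring of mothers fed genistein with tumours from offspring of control-fed mothers, asking what maternal exposure leaves in gene expression and DNA methylation. RNA was measured in 3 control and 4 maternal genistein tumours, and RRBS in 3 and 4. At the 4327 listed CpG sites the control libraries held 226194, 219417 and 203672 reads, with a median coverage of 41, 39 and 35. The maternal genistein libraries held 185613, 174933, 210974 and 113967 reads at those sites, with a median coverage of 33, 30, 37 and 18. Replicate 4 of that group is thus the least precise, and these totals cover the listed sites, not the whole libraries. RNA depth per library was not analysed here.

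In maternal genistein tumours 9 of 10 called basal epithelial genes were higher and all 6 called immediate early genes lower. Neither list passed Fisher's exact test after Benjamini-Hochberg adjustment (adjusted p = 0.398 and 0.124). In the authors' deposited table, Trp63, the transcription factor of basal epithelium, had a log2 fold change of 4.73 (SE 0.71). The basal keratins Krt5 and Krt6a had log2 fold changes of 4.49 (SE 0.78) and 4.18 (SE 0.66) in the authors' deposited table. Nr4a1, an orphan nuclear receptor induced within minutes of growth stimulation, was lower by the authors' deposited table, with a log2 fold change of -2.49 (SE 0.37).

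The authors' deposited table listed 1324 genes at a DESeq adjusted p under 0.05, of which 768 were higher and 556 lower. At a DESeq adjusted p under 0.01 the authors' deposited table kept 698. The edgeR columns of the authors' deposited table put 933 of the 1324 genes at a false discovery rate under 0.05, and all 1324 had the same sign with both tools. The median log2 fold change in the authors' deposited table was 1.68 among higher and -1.47 among lower genes. The direction rests on the reading of the fold change given with the processing, and whether 1 tumour carries a fold could not be examined from this table.

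Gsc and Uts2r had the largest positive folds among called genes with a mean normalised count of at least 50. Gsc, a homeobox gene of the gastrula organiser, reached 8.82 (SE 1.87) on the log2 scale in the authors' deposited table, and Uts2r, the urotensin II receptor, 8.48 (SE 0.72). Others in this group of the authors' deposited table were Dgkk at 7.30, Htra4 at 6.82, Kcnb2 at 6.39 and Cbln1 at 6.01. Dab1, an adaptor of reelin signalling, stood at 5.99 in the authors' deposited table, with Dlx6 at 5.78 and Foxe1 at 5.76. The lowest p-values among higher genes in the authors' deposited table were those of Slpi, a secreted protease inhibitor (log2 fold change 3.50, DESeq adjusted p = 4.05e-44), Plch2 (4.40), Uts2r, Sdk1 (4.58) and Pi15 (5.38).

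Among lower genes, Gjb1, which encodes a connexin, had the largest fold in the authors' deposited table, with a log2 value of -7.77 (SE 1.20). Bcat1, a branched-chain amino acid transaminase, followed at -6.56 (SE 1.35) in the authors' deposited table. The others by size in the authors' deposited table were Fstl4 at -6.27, Reln at -5.85, Capn6 at -5.70, Ugt8a at -5.68, Sult6b2 at -5.50, Adamts20 at -5.40, Ppp2r2c at -4.88 and Slc6a15 at -4.60. By p-value the authors' deposited table put Rspo3, a Wnt agonist, first (log2 fold change -4.39, DESeq adjusted p = 7.44e-17), then Elmo1 at -2.39, Etnk1 at -3.12, Ugt8a, and Tpd52l1 at -2.12.

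Of the 20 basal and myoepithelial genes, 10 were called in the authors' deposited table, 9 higher and 1 lower. Mylk, a myosin light chain kinase, was at 3.05 (SE 0.51) on the log2 scale in the authors' deposited table, and the exception was Sox10 at -2.89 (SE 0.75). The balance of this list against the other called genes gave a Fisher's exact p of 0.0519, adjusted p = 0.398. That test leaves out the direction that called genes share by chromosome. Trp63 and Mylk lie on chromosome 16, where 43 of 52 called protein-coding genes were higher. Krt5 and Krt6a lie on chromosome 15, where 65 of 83 were lower. The other called members were not weighed in this way. Called luminal genes split 4 to 4 in the authors' deposited table. Pgr, the progesterone receptor, was at 2.96 and Ly6a at 1.71 there, against Elf5, a regulator of alveolar cells, at -2.68 and Areg at -2.64. Pgr had a low mean normalised count of 39.2. Milk genes gave 1 higher (Muc1, 1.94) and 2 lower (Spp1, -1.81, and Mfge8, -0.66) in the authors' deposited table. Mfge8 had an edgeR false discovery rate of 0.19 there. Of the differentiated keratinocyte list 1 gene was called, Dsg1a, which was higher at 4.02 in the authors' deposited table. The keratinocyte adhesion genes Cdsn at 3.57 and Dsg3 at 2.49, outside the lists and chosen after their values were seen, were also higher in the authors' deposited table.

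**Figure D1:**
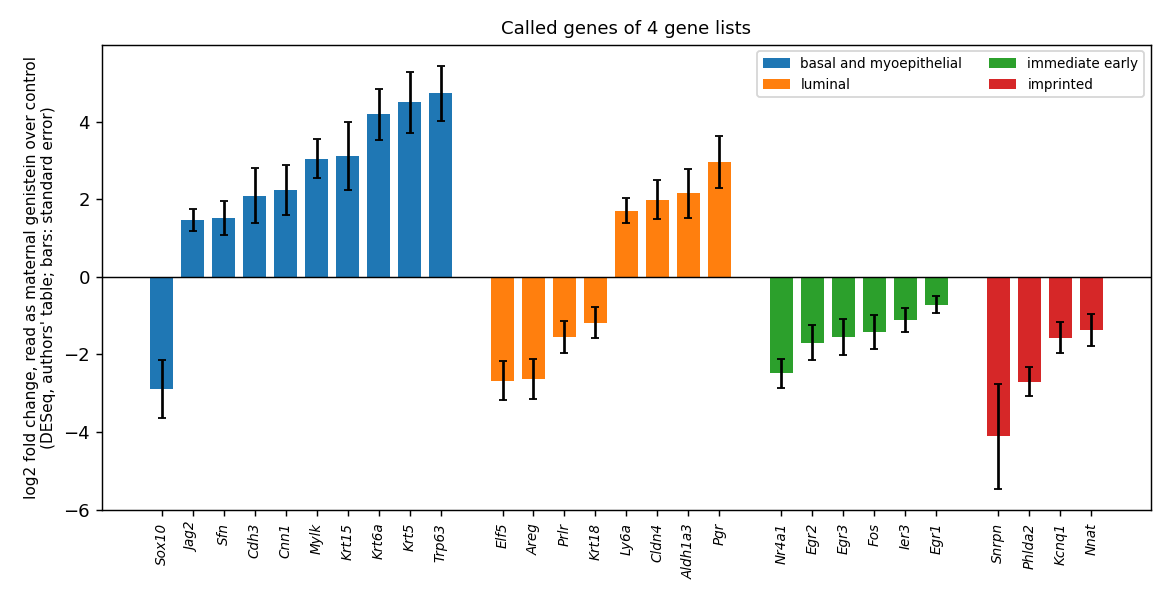
DESeq log2 fold changes, read as maternal genistein over control, of called genes in 4 gene lists, from the authors' deposited table; bars give the fold and whiskers its standard error. Of the basal genes 9 of 10 lie above 0, and all 6 immediate early and all 4 imprinted genes lie below 0.

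All 6 called immediate early genes were lower, among them Egr2 at -1.69, Ier3 at -1.10 and Egr1 at -0.72 in the authors' deposited table. Their Fisher's exact p was 0.0054 and the adjusted p was 0.124. Egr1 and Egr3 had edgeR false discovery rates of 0.098 and 0.0526 in the authors' deposited table. With an edgeR rate under 0.05 required, 4 genes stayed, with a Fisher's exact p of 0.0388 and an adjusted p of 0.558. The 4 called members of the imprinted list were lower as well: Phlda2 at -2.70, Kcnq1 at -1.56, Nnat at -1.37 and Snrpn at -4.11 in the authors' deposited table. That list had a Fisher's exact p of 0.0309 and an adjusted p of 0.355. Phlda2, Kcnq1 and Snrpn lie on chromosome 7, where 41 called protein-coding genes were lower and 22 higher. Nnat lies on chromosome 2, with 86 lower and 19 higher, and had an edgeR false discovery rate of 0.114 in the authors' deposited table. The Fisher's exact test leaves this shared direction by chromosome out, so it cannot show that imprinting matters. No list passed the adjusted threshold; 2 had an unadjusted p under 0.05.

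Growth factor genes gave 2 higher and 4 lower calls: Fgfr2 was at 3.57 and Erbb4 at 4.17, against Nrg1 at -2.76, in the authors' deposited table. Of the mesenchymal transition genes 1 was higher (Snai2, 2.07) and 4 were lower, including the intermediate filament gene Vim at -1.71, Twist1 at -2.54 and Itgb3 at -1.70, in the authors' deposited table. Estrogen-responsive genes had 1 higher and 3 lower, with Ccnd1 at -2.21 and Egr3 at -1.55 in the authors' deposited table. Wnt, Notch and Hedgehog genes split 2 to 2 in the authors' deposited table, with Gli2 at 2.41, Sfrp1 at 1.26, Lef1 at -3.02 and Hey1 at -2.09. Homeobox and related regulators gave 3 higher and 1 lower in the authors' deposited table: Sox9 at 1.38, Pax6 at 3.76, Hoxa9 at 4.35 and Irx3 at -1.72. Hoxa9 had a low mean normalised count of 15.2 there. The hypoxia genes Car9 at 2.29 and Higd1a at 0.95 were higher in the authors' deposited table, and the lipid genes Me1 at 1.14 and Srebf2 at -1.02 went apart.

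Markers of other cell types were called singly. In the authors' deposited table these were Trbc2 of T cells, which has a near-identical copy, at 4.08, Igha of plasma cells at 5.75, Arg1 of macrophages at 1.88, Flt1 of endothelium at 1.56, Tnni2 of skeletal muscle at 3.74 and Gria1 of neurons at 3.57. The neutrophil-associated gene Lcn2 was lower at -1.25 in the authors' deposited table. Single calls also came from the mitosis list (Bub1b, -1.07), the p53 list (Gadd45b, 1.37) and the chromatin list (Ep300, -0.94) in the authors' deposited table. Gria1 had a low mean normalised count of 27.9 in the authors' deposited table. No fibroblast, adipocyte, interferon, ribosomal or respiratory chain gene of the lists was called.

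Called genes were not spread evenly by direction over the genome. Of called protein-coding genes 98 of 113 on chromosome 9, 88 of 104 on chromosome 4 and 59 of 68 on the X chromosome were higher. On chromosome 2, 86 were lower and 19 higher, and lower genes made up 65 of 83 on chromosome 15 and 42 of 52 on chromosome 13. Over 1197 genes on 20 chromosomes a permutation test of direction by chromosome gave p = 1e-05, the smallest that 100000 resamples can give. Relative RRBS coverage of chromosome 9 was 0.35 higher, and of chromosome 15 0.35 lower (difference -0.35), in the maternal genistein libraries on the log2 scale. Without each library in turn these differences lay between 0.26 and 0.49 for chromosome 9 and between -0.45 and -0.24 for chromosome 15. Single libraries of the groups overlapped on both, with control replicate 1 at 0.06 and maternal genistein replicate 3 at 0.03 on chromosome 9, and maternal genistein replicate 1 at 0.11 and control replicate 1 at 0.08 on chromosome 15. The share of higher genes and this coverage difference had a Pearson's r of 0.901 and a Spearman's rho of 0.913 (permutation p = 1e-05 for each). Without the 2 chromosomes farthest from the median, r was 0.887. The sign of r was used to read the direction of the fold changes, so only its size was tested. On distal chromosome 6, beyond a boundary of 140 Mb chosen after the values were seen, 17 of 19 called genes were lower, against 10 of 59 on the rest of the chromosome (Fisher's exact p = 1.64e-08). That segment holds Bcat1, Etnk1 and Sult6b2. At 9 listed sites there, control replicate 2 had a relative coverage of 2.11 on the log2 scale, while the other 6 libraries lay between -0.71 and -0.13.

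**Figure D2:**
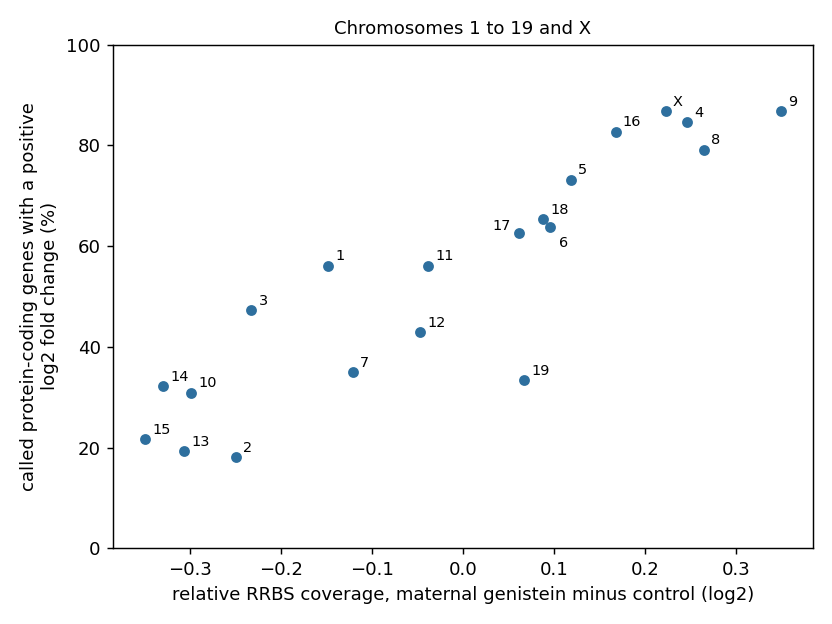
Share of called protein-coding genes with a positive log2 fold change, in percent, against the difference in relative RRBS coverage between maternal genistein and control libraries on the log2 scale; each point is 1 chromosome. Chromosomes 4, 8, 9, 16 and X lie at the upper right and chromosomes 2, 10, 13, 14 and 15 at the lower left, with r = 0.901.

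In DNA, the gene-assigned sites with the lowest quasi-binomial p lay apart between the groups in both directions, but none of these 10 sites passed Benjamini-Hochberg adjustment (adjusted p = 0.103). At a site in an intron of Tprg (chromosome 16, position 25385320, mm10) the level was 82.1% ± 5.91 (SD, n = 3) in control and 17.6% ± 7.26 (SD, n = 4) in maternal genistein tumours, at 64 to 167 reads. In the 5' untranslated region of the X-linked Acsl4, an acyl-CoA synthetase gene (position 142390385), the level was 56.3% ± 4.18 in control and 9.87% ± 7.81 in maternal genistein tumours, at 13 to 106 reads. An intronic site of Dlg5, a scaffold protein gene (chromosome 14, position 24234806), went the other way, with 33.0% ± 2.64 in control and 79.3% ± 4.73 in maternal genistein tumours at 21 to 125 reads. The groups did not overlap at these sites, which were picked for their difference in this same comparison.

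The other sites of this rank were picked in the same way. Another Dlg5 intron site at position 24214801 was at 36.9% ± 9.25 in control and 94.6% ± 4.12 in maternal genistein tumours, at 12 to 76 reads. Also higher there were an intron site of Morn3 on chromosome 5 at 123046591 (2.08% ± 1.45 against 34.0% ± 7.16), an exon site of Ywhag on chromosome 5 at 135911472 (60.3% ± 12.1 against 100%) and an intron site of Csmd1 on chromosome 8 at 16084258 (20.1% ± 17.5 against 89.4% ± 7.22). Lower were intron sites of Tbc1d1 on chromosome 5 at 64193444 (72.2% ± 0.73 against 38.9% ± 4.09), Atp11a on chromosome 8 at 12763444 (98.1% ± 3.35 against 55.3% ± 6.24) and Dagla on chromosome 19 at 10267213 (68.1% ± 13.4 against 1.79% ± 3.57). Coverage of the sites in these genes lay between 10 reads, at Csmd1 and Dagla, and 125 reads, at Tbc1d1. The quasi-binomial p of these 10 sites lay between 0.00015 and 0.000814.

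**Figure D3:**
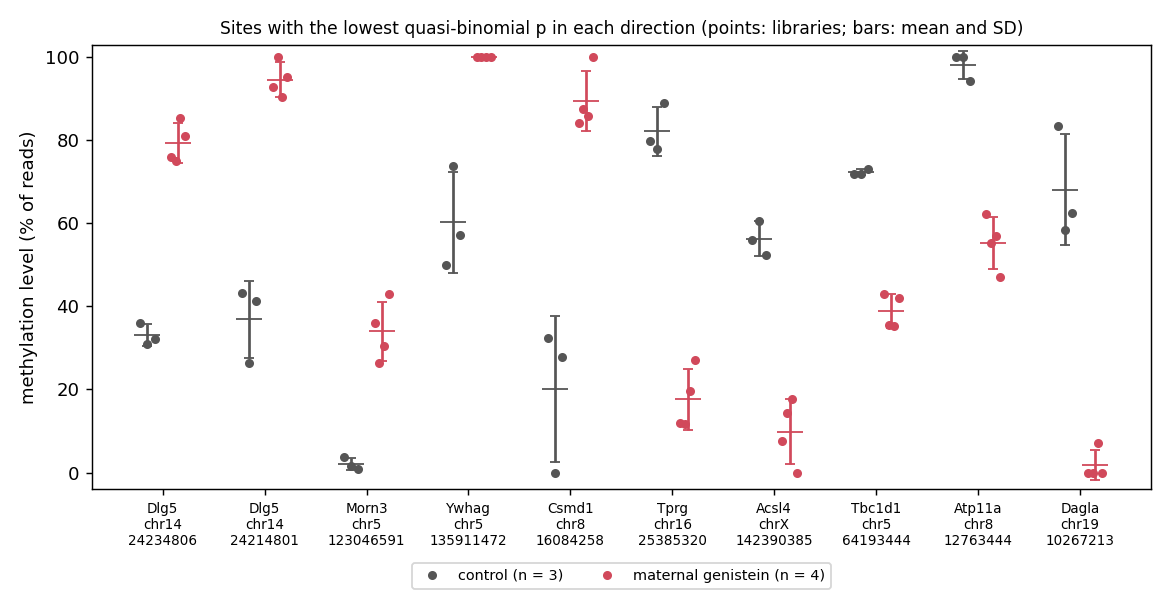
Methylation level in percent of reads at the 10 gene-assigned sites with the lowest quasi-binomial p, 5 in each direction; points are libraries, and bars give the mean and SD of 3 control and 4 maternal genistein libraries. The groups do not overlap at any of the 10 sites, for example 33.0% against 79.3% at the first Dlg5 site.

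Of the 4327 sites the authors listed, 2297 were higher and 2030 lower in maternal genistein tumours. With the spread between tumours in the model, 1369 sites (31.6%) had a quasi-binomial p under 0.05, of which 742 were higher and 627 lower. After adjustment 2 sites passed, both between Dhx40 and Ypel2 on chromosome 11 (positions 86868535 and 86868545), with differences of -79.3 and -66.4 points. They were chosen after their values were seen, and no site passed when any of the 7 libraries was left out. At a coverage of at least 20 reads 7 sites passed, and with a chi-square in place of the F reference 1731. The group levels did not overlap at 1202 sites (27.8%), where chance gives 5.71% for sites not selected beforehand. Within groups, the levels at a site spanned 38.8 points on average in control and 46.4 points in maternal genistein tumours, while the median difference between groups was 32.3 points.

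The share of listed sites with lower methylation was 46.9% (exact binomial 95% interval 45.4 to 48.4), and 46.1% of 3539 clusters of sites within 1000 bases (44.4 to 47.7). By location, 29 of 39 sites in 5' untranslated regions and 58.1% of sites upstream of genes were lower, while 35 of 47 sites in 3' untranslated regions and 32 of 46 in exons of noncoding RNAs were higher. Of 1638 intronic sites 719 were lower, and differences between locations were not tested. The X chromosome had 109 of its 158 sites lower, against 1921 of 4167 on the autosomes. Counted as clusters, the difference between X and autosomes had a Fisher's exact p of 0.000108. Clusters on the X chromosome of a tumour are not independent, and the sites were selected for a group difference. This p-value therefore does not measure the spread between tumours.

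Regions listed by the authors were mostly lower in maternal genistein tumours, while 46.9% of the listed sites were lower. These shares rest on largely different CpGs, since 20 of the 139 regions hold a listed site. Every listed site had at least 10 reads in every library, and whether the CpGs of the regions did was not examined. The shares are therefore not directly comparable. The authors' deposited table listed 139 regions, 92 lower (66.2%, exact binomial 95% interval 57.7 to 74.0) and 47 higher, with a median length of 73 bases and a median of 6 CpGs. On the X chromosome 18 of 19 regions were lower, against 74 of 120 elsewhere (Fisher's exact p = 0.00354). Regions of the same tumours are not independent either, so this p-value does not measure the spread between tumours. In the authors' deposited table a region at a CpG island upstream of Jade3 (X chromosome, 20425224 to 20425397, 16 CpGs) was at 77.5% in control and 5.72% in maternal genistein tumours. A region in Wnt10b, a Wnt ligand gene (chromosome 15, 98774106 to 98774160), was at 87.2% in control and 18.7% in maternal genistein tumours in the authors' deposited table. Regions near Uaca (chromosome 9) and in an intron shared by Anxa8 and A630023A22Rik (chromosome 14) had differences of -67.3 and -73.9 points in the authors' deposited table.

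Higher regions included 1 in Nr4a1, running from an intron into an exon (chromosome 15, 101269966 to 101270418, 8 CpGs), at 24.5% in control and 87.8% in maternal genistein tumours in the authors' deposited table. Others of large size in the authors' deposited table lay in Fam160b1 (67.3 points) and in exons of C2cd4c (61.3 points) and Rai1 (58.2 points). The named regions of Jade3, Wnt10b, Anxa8, Nr4a1, C2cd4c and Rai1, the intergenic region on chromosome 9, and all regions on the X chromosome hold no listed site. Their spread between tumours was therefore not examined. Reads per library were used for the 20 of 139 regions that hold a listed site. They were summed over the listed sites alone. In some regions these are a small part of the CpGs, such as 2 of 11 in Irx4. On those sites 12 regions had an exact permutation p of 0.0286 and 8 did not pass, with an exact permutation p of up to 0.257. Where only a part of the CpGs was listed, this does not test the whole region. The sites had been listed for this comparison, so these p-values are not independent evidence. In the Fam160b1 region the levels were 24.2% ± 28.2 (SD, n = 3) in control and 91.8% ± 5.52 (SD, n = 4) in maternal genistein tumours (exact permutation p = 0.0286).

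Some genes changed in both assays. In Nr4a1 regional methylation was higher and expression lower by the authors' deposited table, but the region holds no listed site, so its levels per library were not examined. Trp63 had a region in an intron (chromosome 16, 25835935 to 25835966) at 85.6% ± 6.32 (SD, n = 3) in control and 33.2% ± 19.7 (SD, n = 4) in maternal genistein tumours over 4 listed sites and 54 to 286 reads (exact permutation p = 0.0286), together with its higher expression. Irx4 was chosen after its values were seen, and 2 of the 11 CpGs of its region are listed sites. Over these, levels were 58.0% ± 41.2 in control and 27.5% ± 20.9 in maternal genistein tumours, and the groups overlapped (exact permutation p = 0.257). For the whole Irx4 region the authors' deposited table gives 63.7% and 17.4%, without levels per library. In Sdk1 and C2cd4c both regional methylation and expression were higher by the authors' deposited table, again in regions without a listed site. In all, 25 called genes held such a region; 12 paired lower methylation with higher expression, 5 higher with lower, 6 were higher in both and 2 lower in both (odds ratio 0.2, Fisher's exact p = 0.177). The other reading of the fold change gives an odds ratio of 5. By symbol, 176 called genes held a listed site.

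The integrated table of the authors paired 353 called genes with 533 sites, at a median distance of 31222 bases from the gene's lower genomic coordinate, whatever its strand. Taking the site with the largest difference per gene, 121 genes were higher in both, 44 lower in both, 108 lower in methylation and higher in expression, and 80 the reverse. With the fold change read as above, opposite directions were more frequent than independence gives (odds ratio 0.616, Fisher's exact p = 0.0425). The other reading of the fold change turns this into more frequent same directions, with an odds ratio of 1.62 and the same p. The Fisher's exact test takes genes as independent and leaves the shared direction by chromosome out. On the X chromosome 59 of 68 called protein-coding genes were higher and 109 of 158 listed sites lower. The test was not run without the X chromosome, so it cannot show a relation within single genes. Fisher's exact p was 0.117 with the lowest-p site per gene, 0.078 for genes with all sites in one direction, 0.225 at an expression adjusted p under 0.01 by DESeq, and 0.346 for the 176 genes named by the site's own annotation. Over all 589 pairs, which repeat genes and so are not independent, it was 0.00158 (odds ratio 0.575). At promoter sites, 24 genes gave an odds ratio of 0.692 (Fisher's exact p = 1). Exon, intron and intergenic sites had Fisher's exact p-values of 0.566, 0.146 and 0.449 (Benjamini-Hochberg adjusted p = 0.755, 0.585 and 0.755 over 4 locations).

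Promoter sites were ranked by their difference in this same comparison, so their exact p-values are not independent evidence. Cyp21a1, a steroid hydroxylase gene (chromosome 17, position 34804775), was at 76.6% ± 24.3 (SD, n = 3) in control and 24.3% ± 16.9 (SD, n = 4) in maternal genistein tumours, at 29 to 113 reads (exact permutation p = 0.0286). Its expression was higher, with a log2 fold change of 4.28 (SE 1.12) in the authors' deposited table; its counts are uncertain because of a near-identical pseudogene. Fut2, a fucosyltransferase gene, had 72.3% ± 21.4 against 24.1% ± 12.3 at a 5' untranslated site (chromosome 7, position 45655513, 14 to 54 reads, exact permutation p = 0.0286), and a log2 fold change of 2.56 in the authors' deposited table. Tmem47 on the X chromosome (position 81070335, 13 to 75 reads) had 48.4% ± 23.3 against 1.06% ± 2.11 (exact permutation p = 0.0286), and lower expression (-2.09 in the authors' deposited table). For Actr3b, Dab1 and AI839979 the pooled methylation differences in the authors' deposited table were -39.4, -35.8 and -33.3 points, with higher expression. The Dab1 site is annotated as upstream but lies inside the gene, at a signed distance of -747944 bases from its lower genomic coordinate. The levels per library did not pass the exact permutation test for these 3 genes (p = 0.0571, 0.143 and 0.114). The remaining promoter sites of this rank are annotated to a neighbour of the called gene, namely Tmem100 for Pctp, Tal1 for Pdzk1ip1, Slc25a41 for Tubb4a and Krt75 for Krt90.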

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

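The tests of dispersion, other splits, single libraries and X coverage in this part were chosen after the results were seen. In 33 sets of 4 maternal genistein values 4 had 1 library far from the others; chance gives this in about 1 of 20 sets. In 3 of the 4 the other libraries were all at 0%, where any methylated read meets the criterion and that rate does not hold. At the Dagla site maternal genistein replicate 3 was at 7.14% while the other 3 were at 0%. At the Tmem47 promoter site the same replicate was at 4.23% and the others at 0%. At the intragenic Dab1 site, at a signed distance of -747944 bases from the gene's lower genomic coordinate, maternal genistein replicate 2 was at 9.09% and the others at 0%. In the Fam160b1 region maternal genistein replicate 1 was at 100% and the others between 88.5% and 89.9%.

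The number of listed sites falls when tumours rather than reads are the unit. The median dispersion over sites was 8.14, where 1 is the value for reads that vary only by sampling, so spread between tumours that the deposited test leaves out is a candidate explanation for much of the list's length. Of the 35 splits of the 7 libraries into 3 and 4, only the real 1 gave as many as 1369 sites with a quasi-binomial p under 0.05, and the highest of the others gave 859. The sites had been listed for the real split, which favours it, so this count cannot exclude chance. Simulated tumours with this spread gave a pooled-read p under 0.05 at 53.3% of unchanged sites. The spread was taken from sites selected for a large pooled difference, and a p under 0.05 is looser than the criteria of the list. This rate therefore does not give the share of false calls among all CpGs tested or in the list.

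X chromosome sites were lower in maternal genistein tumours more often than autosomal ones, with mean levels of 48.8%, 50.9% and 55.9% in control and 36.2%, 39.7%, 43.6% and 40.1% in maternal genistein libraries. Without each library in turn the share of lower X sites stayed at least 21.7 percentage points above the autosomal share. At least 99.1% of all listed sites kept their direction then, because they had been selected for a large difference, so this cannot tell whether 1 library carries the pattern. The groups overlapped by 0.32 on the log2 scale in relative X coverage, so the number of X copies may or may not contribute, since coverage cannot separate the active from the inactive X. An effect of maternal diet on X methylation stays open and was not tested separately.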

How the results depend on the processing

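Choices added after seeing the data were the edgeR filter, the chi-square reference, the authors' q-value, the distal chromosome 6 filter, the balance of sites with quasi-binomial p under 0.05 and the same-gene matching. Of 90 alternative values 65 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. Some of the 65 could not differ, because every listed gene or site already met the alternative. Among them were an unadjusted p under 0.05 for RNA, the minimums on the site difference, the lower coverage minimum and a q-value under 0.01. The tally therefore overstates how stable the results are. The 1324 called genes became 698 at an adjusted p under 0.01, by construction of a stricter threshold. The 2 sites past the quasi-binomial adjustment became 0 at an adjusted p under 0.01, 1 after merging sites within 1000 bases, 7 at a coverage of at least 20, 1731 with a chi-square reference and 4327 with the authors' q-value. Leaving out 1 library gave 0 to 0 sites, with 985 to 1271 at an unadjusted p under 0.05. The 1369 sites with an unadjusted p under 0.05 became 36 under 0.001, 437 at a coverage of at least 20 (1230 sites tested) and 2413 with the chi-square reference. With the replicate number as a replicate block over replicates 1 to 3, 0 sites passed and 892 had an unadjusted p under 0.05, in 6 libraries; same-numbered libraries did not deviate together (correlations 0.022, 0.009 and -0.032), so they share only a number. Regions of at least 100 bases numbered 56 of 139, by construction. The integration p of 0.0425 became 0.117 with the lowest-p site, 0.078 for genes with sites all one way, 0.225 at an expression adjusted p under 0.01, 1 at promoter sites only and 0.346 for sites annotated to the same gene, with the odds ratio under 1 in each; fewer genes enter all but the first, and the cause was not tested further. The 176 genes shared by symbol became 25 with regions in place of sites. Shares of lower sites lay between 46.8% and 47.7% without each library, which the selection of sites largely fixes, and no gene list passed under any of its 4 alternatives. An adjusted p under 0.1 for RNA gave no value, since the table ends at 0.05. Coverage limits maternal genistein replicate 4 most, at a median of 18 reads.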

Other observations

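The tests in this part were chosen after the results were seen, except the correlation within chromosomes and the test of genes by distance to a site. Called genes of the MAPK activity score, 10 genes known to report signalling through ERK, all lay on the lower side in the authors' deposited table: Etv5 at -2.77, Ccnd1 at -2.21, Phlda1 at -1.66, Dusp6 at -1.28 and Etv4 at -1.28. The 5 lower and 0 higher calls differed from the other called genes with a Fisher's exact p of 0.0129. Together with lower immediate early genes this is in line with the hypothesis of lower ERK output in the maternal genistein tumours, or of higher output in 1 or more control tumours. RNA values per library, which would separate these, were not used here. Dusp6 and Phlda1 lie on chromosome 10 and Ccnd1 on chromosome 7, where most called genes were lower. Etv5 lies on chromosome 16 and Etv4 on chromosome 11, where most were higher. Of the immediate early genes, Nr4a1, Egr2 and Egr3 lie on chromosomes 15, 10 and 14, where most were lower. Ier3 and Egr1 lie on chromosomes 17 and 18, where most were higher. The immediate early list did not pass adjustment (Fisher's exact test, adjusted p = 0.124). It was also drawn up as a list of dissociation and handling stress genes, and a difference in tissue handling was not tested.

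A candidate explanation for the shared direction of called genes along chromosomes is DNA copy number that differs between the tumours. Over 20 chromosomes the share of higher genes followed relative RRBS coverage with r = 0.901, and r stayed between 0.787 and 0.905 without each library in turn. The sign of this relation was used to read the direction of the folds, so only its size bears on the hypothesis. Reads shared by neighbouring genes do not account for it: called neighbours more than 1 Mb apart had the same direction in 60.6% of 513 pairs, against 50.7% with shuffled directions (permutation p = 1e-05, the smallest possible). Within chromosomes, over 167 bins of 10 Mb, the relation was not seen (r = 0.038, permutation p = 0.67), which leaves open how far it reaches below whole chromosomes; GC content was not tested. A gain of distal chromosome 6 in control replicate 2 may thus contribute to the lower Bcat1 and Etnk1 calls, if that tumour was also among those used for RNA, which the labels do not say. Whether such gains relate to maternal diet or differ by tumour was not tested.

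Genes with a listed site within 5000 bases of their lower genomic coordinate numbered 57. Their odds ratio between methylation and expression was 0.328, or 3.05 with the other reading of the fold change, with a Fisher's exact p of 0.0587. The distance was meant to pick sites near gene starts, but it ignores the strand, so this value cannot tell whether the directions are opposite there.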
